A study of Mus musculus with 6 samples.

How the data were processed

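Liver RNA from 6 mice was measured on 6 NimbleGen single-colour expression arrays, 1 mouse per array. Per the labels, the mice were wild-type C57 BL/6 males, total RNA was labelled with Cy3, and the replicates of each group came from separate treatments. The groups were taken from the treatment given in the labels: 3 mice received LPS and 3 received LPS with GalN. Replicate numbers 1, 2 and 3 come from the sample titles.

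The authors deposited 1 table of RMA intensity per array, per the file headers and the submitters' processing notes, with values on the linear scale. RMA (robust multi-array average) corrects background, normalizes between arrays and summarises the probes of a target into a single value. The version of RMA and its settings are not given in the sources used here. Per the labels, the array design covered 44170 genes with 3 probe pairs each. The files held 44170 target rows per array, of which 44155 were summarised from 3 probes, 9 from 2 and 6 from 1. The sorted values of the 6 arrays nearly coincided, so a global rise or fall of RNA per cell would have been removed by the normalization. A deposited value table of the whole series, also in RMA intensity, held the 18076 rows with an intensity of at least 50 on all 6 arrays, found by matching it to the arrays, and served only as an alternative.

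Each file also held a row summarising 5000 random probes, which is used here as the background level of its array. A gene not above that row on any array of a group has only a bound in that group. Its fold is then given as "at least", from the mean of the brighter group against the mean, per array, of the higher of the background row and the gene's own value. A named gene past the threshold with a group mean above a log2 of 15, near the top of the scale, also has its fold given as "at least"; this limit was chosen after the values were seen.

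The files describe targets by a gene description and by mm9 coordinates of the gene, not by the positions of the probes. Whether a target lies in an exon or an untranslated region was therefore not examined. Symbols were assigned from the descriptions, from sequence identifiers matched to a table of RefSeq genes used for names and gene classes only, and from a hand-made table of 1081 gene names; some entries of that table were added after values had been seen. A symbol was assigned to 8097 rows, 19440 had a gene name only, and 16633 had neither. Rows of a gene were joined by symbol or, without a symbol, by full gene name and chromosome. The fixed design had foreseen joining by symbol only; joining by name was chosen after seeing how the files name genes, and the symbol-only version is among the alternatives. Of several rows, the row with the highest mean over all 6 arrays was kept, which does not look at the groups. This left 36240 features, 19607 of them named (5935 by symbol and 13672 by gene name only). Of the 5564 features with several rows, 0 had rows past the threshold in both directions. Among 311 called features with several rows, all rows had the sign of the call in 280, and every row passed the threshold in 135.

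Intensities were converted to log2, and LPS/GalN was compared with LPS by limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3 with the group as the only term, two-sided. P-values were adjusted by the Benjamini-Hochberg method over all 36240 features. Adjusted p under 0.05 was the threshold, and the spread of each gene was moderated with 4.01 prior degrees of freedom. No filter on dim features was applied. Signed differences are LPS/GalN minus LPS.

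Gene lists, thresholds, the rule for named genes and 15 alternatives were fixed before the data were examined. The 41 lists cover pathways and cell types of liver and were tested with limma's camera, with a preset inter-gene correlation of 0.01, over the named features and Benjamini-Hochberg adjustment over the lists. Camera compares a list with the other named genes. An estimated correlation and fry, which tests whether the members move on balance in 1 direction, were alternatives. Lists with fewer than 5 measured members would have been left out, and all 41 were tested. Counts of called members are given over all features and adjusted over the list alone.

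The rule for named genes took 3 parts. The first part was the 10 largest rises and the 10 largest falls among named genes past the threshold, with groups that did not overlap and a mean above the median of all features. Clone names and genes that the reference classes as pseudogenes were skipped. The second part was up to 4 members with the smallest p from each list past the set test or with at least 3 called members, in the direction of most of its called members, and up to 2 in the other direction. The third part was a set of fixed genes given whatever their result. The rule gave 98 genes, of which 2 are not reported here, and genes named outside it are said to be chosen after their values were seen.

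The steps were tested on simulated data before use. With the 6 arrays' own means and spread and 200 of 36240 genes changed, log2 changes of 0.5 and of 1 gave 0 recovered genes, a log2 change of 2 gave 104 (52%) with 4 false calls, and no change gave 0 calls. The number of arrays limits the precision, since changes of up to 2-fold were not recovered in this simulation.

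Alternatives were the replicate number as a block, leaving out each array in turn, a further quantile normalization, cyclic loess, centring on ribosomal protein genes, filters on dim features at the median and at the 25th percentile, other ways to join rows, eBayes with trend and robust fitting, array weights, the deposited value table of the series, and a stricter adjusted p under 0.01. After seeing the data, 4 more were added: joining rows by symbol only, setting values below background to the background row, and leaving out the 2 arrays with thymus transcripts or the 2 with small intestine transcripts. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and statmod 1.5.0 and jsonlite 2.0.0 were loaded in R.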

Results

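Gene expression was measured in the livers of 6 male wild-type mice. Of these, 3 received 0.01 µg of LPS (lipopolysaccharide, a bacterial cell wall component sensed by the receptor Tlr4). The other 3 received the same dose of LPS with 20 mg of GalN (D-galactosamine, an amino sugar that lowers the uridine nucleotides of hepatocytes). Treatment lasted 2.5 h in both groups. No untreated mice and no mice given GalN alone were analysed here, so a lower level in LPS/GalN cannot be assigned to weaker induction or to loss of a transcript. The median intensity of an array was between 60.4 and 63.1, and the background level from random probes lay between 31.3 and 34.7. Between 17.5 and 22% of targets lay at or below that level. Across genes, which are not independent replicates, Pearson's r of log2 values was 0.952 to 0.970 within groups and 0.916 to 0.947 between groups. The first principal component held 46.6% of the variance and separated the groups.

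The comparison asked which liver transcripts differed when GalN was given together with LPS. Livers of LPS/GalN mice held lower levels of many inflammatory and interferon-response transcripts. Lower past the threshold were 32 of 36 interferon-stimulated, 14 of 27 acute phase, 8 of 23 cytokine and 9 of 27 chemokine genes. By camera these lists passed with the preset correlation but not with an estimated one (adjusted p between 0.0872 and 0.108). Tifa, an adaptor of NF-kB signalling, was 52.8-fold lower, the acute phase gene Saa3 was at least 49.4-fold lower, and Cxcl9, a chemokine for T cells, was 48.2-fold lower. Genes of 38 proteins that hepatocytes secrete had a median log2 change of -0.01. Many of them read near the top of the scale, where a change can be hidden, and the 13 with a mean log2 below 14, a limit chosen after the values were seen, had a median of 0.029 (quartiles -0.073 and 0.098). Alb, the gene of serum albumin, differed by a log2 of -0.19 ± 0.22 (SE, adjusted p = 0.711), and on LPS replicate 2 it was the brightest row of the array, so its small change says little. Transcripts that rose included Slc25a30, a mitochondrial carrier gene, G6pc, the last enzyme of glucose release, and several genes of endothelial cells. With each array left out in turn, 2 of 21 named rises (Slc25a30 and Spry1) and 58 of 68 named falls passed the threshold each time. G6pc and the endothelial genes Pecam1, Egfl7 and Tie1 did not. Without LPS replicates 1 and 2 the log2 change of G6pc was 1.76, against 3.96 over all arrays.

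In all, 218 features rose and 1073 fell (limma, adjusted p under 0.05), and 214 and 1068 of these changed at least 2-fold. Among named features, 147 rose and 687 fell. At an unadjusted p under 0.05 there were 3076 features higher and 3261 lower. Every array of one group lay above every array of the other for 24% of features, against 10% by chance. Of the called features, 31 were not above background on any array of 1 group. The count of rises depended on single arrays: it was 35 without LPS replicate 1, 42 without LPS replicate 2, 616 without LPS/GalN replicate 1, 59 without LPS/GalN replicate 2 and 110 without LPS/GalN replicate 3, while falls numbered 620 without LPS replicate 1 and 683 without LPS replicate 2. Leaving out LPS/GalN replicates 2 and 3, on which thymus marker transcripts were high, left 1 LPS/GalN array. Leaving out LPS replicates 1 and 2, on which intestine marker transcripts were high, left 1 LPS array. Calls were fewer in both cases, where 1 array stands for a group. The median log2 change of interferon-stimulated genes was then -2.37 and -2.63, against -2.62 over all arrays. That of cell cycle genes was 0.28 and 0.79, against 1.07.

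**Figure D1:**
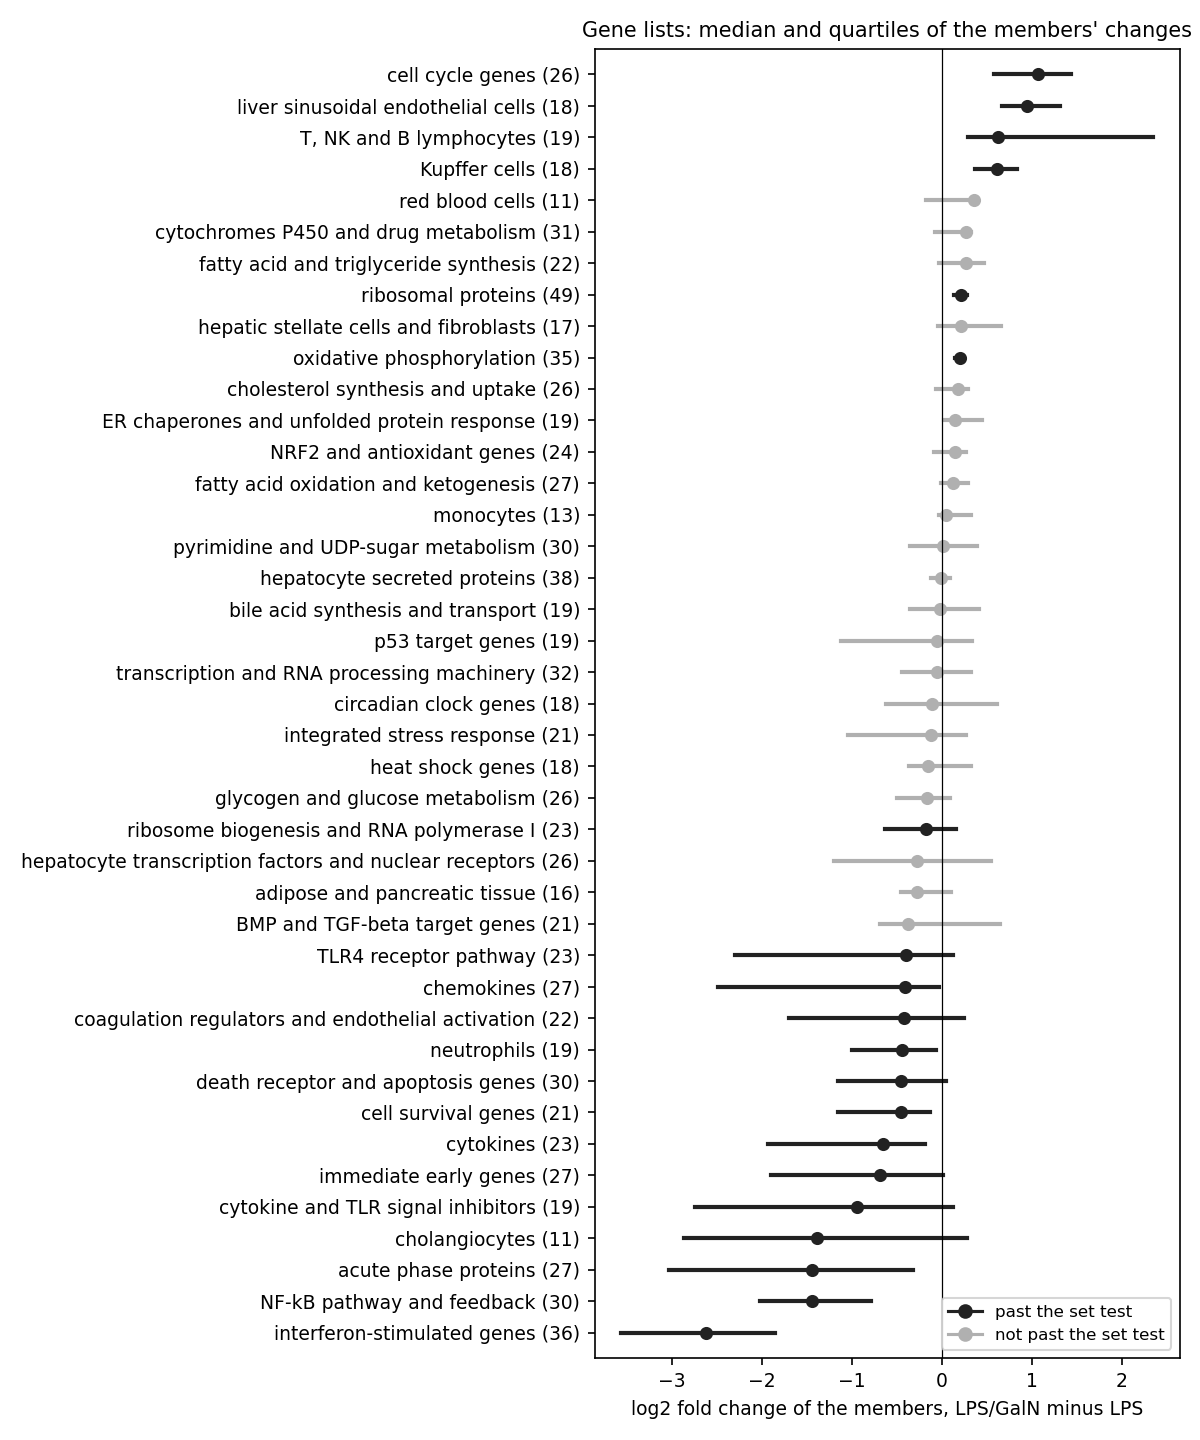
Median log2 change (points) and quartiles (bars) of the members of each of 41 gene lists, LPS/GalN minus LPS; the number of measured members is in brackets, and black marks lists past the set test with the preset correlation. Interferon-stimulated genes lay lowest with a median of -2.62, and cell cycle genes highest with a median of 1.07.

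The largest changes are given for named genes that the reference does not class as pseudogenes. Of the falls, 8 others were larger than the smallest of the 10, chosen here after their values were seen: 5 of targets with no gene name, and those of Mx1 (62.6-fold, adjusted p = 0.00123), Cxcl11 and Mx2 (30.5-fold, adjusted p = 0.000602), interferon-induced genes that the reference classes as transcribed pseudogenes. Among the 10 falls given, Tifa (chromosome 3, 127492830 to 127501307 on mm9) had a log2 intensity of 13.39 ± 0.14 in LPS and 7.67 ± 0.50 in LPS/GalN (SD, n = 3 each), with an adjusted p of 0.000259 by limma. Saa3 (chromosome 7, 53967367 to 53971046) had 15.31 ± 0.011 and 9.68 ± 0.93, with an adjusted p of 0.000599. Saa3 had a second target row near background, with a mean log2 of 4.62, that did not change (log2 0.007). Saa3 and Lcn2 read near the top of the scale in LPS (15.31 and 15.38), so the limit of the scale makes their folds lower bounds, and their ranks are not exact. Cxcl9 (chromosome 5, 92752018 to 92757093) had 14.37 ± 0.27 and 8.78 ± 0.81, with an adjusted p of 0.000539. The mitochondrial nucleotide kinase gene Cmpk2 was 36.3-fold lower and the antiviral gene Ifit1 34-fold lower. Tacc2, a gene of a centrosome-associated protein, was 33.6-fold lower in the brightest of its 5 target rows; the log2 changes of the rows ranged from -5.49 to -0.465, with 3 past the threshold. Tnfaip3, which encodes the NF-kB inhibitor A20, was 24.6-fold lower, the immune checkpoint ligand gene Cd274 was 23.8-fold lower, and the stress-response gene Gadd45g was 22.1-fold lower. Lcn2, an iron-scavenging acute phase gene, was at least 23.4-fold lower with a large spread in LPS/GalN (10.83 ± 1.85). With 1 array left out, the log2 change of Lcn2 lay between -3.59 (without LPS/GalN replicate 2) and -5.435 (without LPS/GalN replicate 1). Lcn2 missed the threshold without LPS replicate 1 (adjusted p = 0.073), LPS replicate 2 (0.0728) or LPS/GalN replicate 3 (0.0701).

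**Figure D2:**
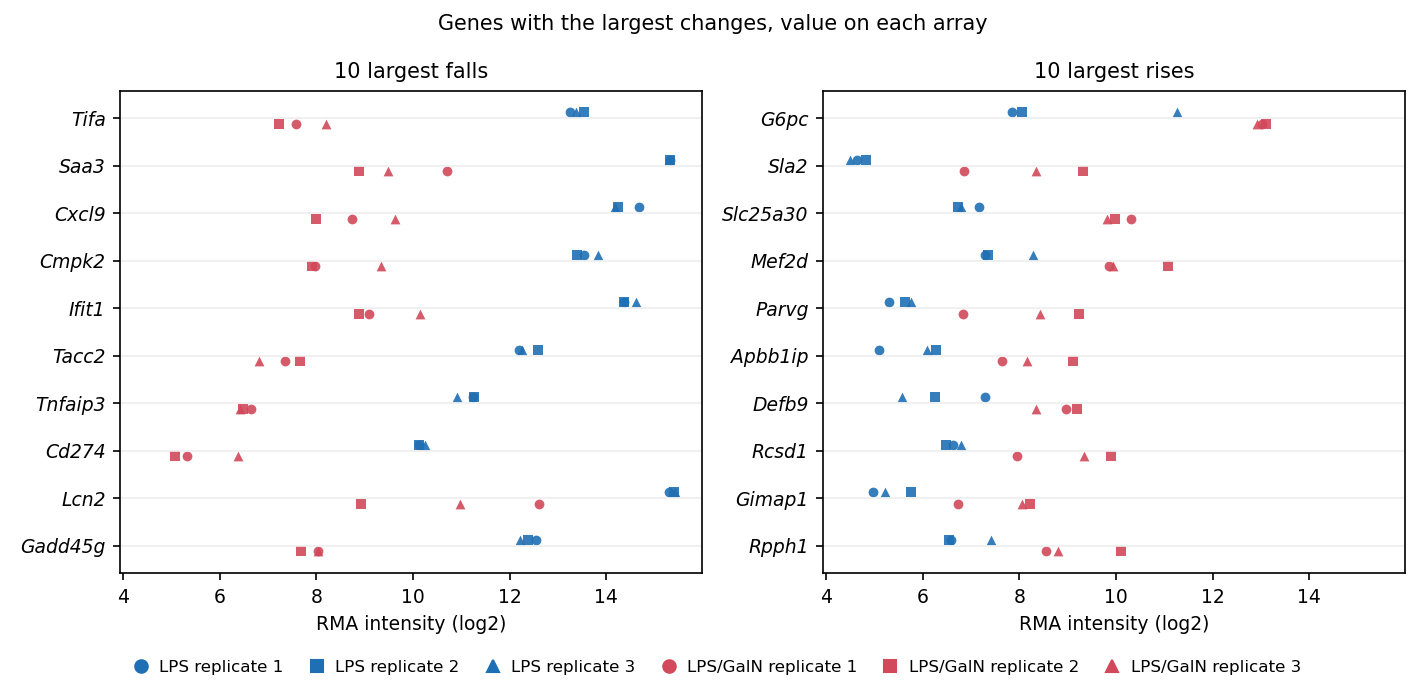
Log2 RMA intensity on each array for the 10 genes with the largest falls and the 10 with the largest rises among named genes that the reference does not class as pseudogenes (blue, LPS; red, LPS/GalN; marker shape, replicate). No array of one group overlaps the other group for any of these genes; G6pc reads 7.85, 8.06 and 11.26 in LPS replicates 1, 2 and 3.

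Interferon-stimulated genes formed the list with the lowest median. Of 36 measured members, 32 fell and 0 rose (35 fell adjusted over the list alone), with a median log2 change of -2.62. The guanylate-binding protein gene Gbp2 was 12.9-fold lower, and the interferon-induced GTPase genes Ifi47 and Tgtp1 were 18.7-fold and 10.9-fold lower. Tgtp1 had 2 of 3 target rows past the threshold (log2 -3.802 to -0.558). Camera gave an adjusted p of 7.01e-40, and the adjusted p = 0.0872 with an estimated correlation. Among acute phase proteins, 14 of 27 fell and 0 rose (18 fell adjusted over the list alone), with a median of -1.44 and a camera adjusted p of 1.22e-17 (adjusted p = 0.108 with an estimated correlation). Saa1, a serum amyloid A gene of hepatocytes, was 14.9-fold lower, and Hamp, which encodes the iron hormone hepcidin, was 6.50-fold lower. Steap4, a metalloreductase gene, was 18.2-fold lower, the interleukin-1 receptor gene Il1r1 was 12.7-fold lower, and the metallothionein gene Mt2 was at least 8.39-fold lower (15.32 in LPS, near the top of the scale).

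Of 23 cytokine genes, 8 fell and 0 rose (11 fell adjusted over the list alone), with a median of -0.65. Il1rn, the interleukin-1 receptor antagonist, was 9.54-fold lower, and Tnfsf10, the death ligand TRAIL, was 7.67-fold lower. The granulocyte growth factor gene Csf3 was 3.94-fold lower and Il27 was 4.03-fold lower. Il1b fell by 2.12 ± 0.39 (log2, SE, adjusted p = 0.0257) and missed the threshold without LPS replicate 1 (adjusted p = 0.0684), 2 (0.104) or 3 (0.0616) or without LPS/GalN replicate 3 (0.0658). Tnf, the cytokine that kills sensitised hepatocytes, differed by -1.21 ± 0.41 with an adjusted p of 0.18, and Il6 by 0.02 ± 0.38 with an adjusted p of 0.985. The 2 target rows of Tnf had log2 changes of -1.212 and -0.363. Il6 read near background (log2 5.58 in LPS and 5.60 in LPS/GalN, with 1 LPS array not above it), so its value says little. The log2 changes of the 3 target rows of Il6 ranged from -0.972 to 0.022. For both genes 0 rows passed the threshold. Il10, an anti-inflammatory cytokine gene, was not above background on any LPS/GalN array; it was at least 1.68-fold lower there, with an adjusted p of 0.13. Of 27 chemokine genes, 9 fell and 0 rose (10 fell adjusted over the list alone), with a median of -0.40. The T cell chemokine gene Cxcl11 was 32.6-fold lower, Cxcl10 at least 6.66-fold (15.44 in LPS, near the top of the scale), the neutrophil chemokine gene Cxcl1 was 18.3-fold lower, and Ccl3 was 8.37-fold lower. Camera gave an adjusted p of 2.76e-07 for cytokines (adjusted p = 0.0937 with an estimated correlation) and of 2.18e-06 for chemokines (adjusted p = 0.0872 with an estimated correlation).

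NF-kB target and feedback genes were lower as a group. In this list 17 of 30 members fell and 0 rose (24 fell adjusted over the list alone), with a median of -1.44 and a camera adjusted p of 1.79e-20 (adjusted p = 0.0445 with an estimated correlation). Bcl3, an atypical inhibitor protein of NF-kB, was 10.2-fold lower, Nfkbiz, which encodes a nuclear member of the same family, was 4.46-fold lower, and the adhesion gene Selp was 4.4-fold lower. Nfkbia, which encodes the classical inhibitor, was 2.4-fold lower with an adjusted p of 0.0179, and missed the threshold without LPS replicate 1 (adjusted p = 0.0837) or 2 (0.0685) or LPS/GalN replicate 2 (0.0528) or 3 (0.0596). Of 19 inhibitors of cytokine and TLR signalling, 9 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -0.94 and a camera adjusted p of 7.13e-08 (adjusted p = 0.0445 with an estimated correlation). Socs3 and Cish, feedback inhibitors of cytokine receptors, were 10.9-fold and 8.84-fold lower, and the phosphatase gene Ptpn2 was 6.99-fold lower. Spry1, an inhibitor of growth factor signalling, was 2.98-fold higher. Of 27 immediate early genes, 8 fell and 0 rose (10 fell adjusted over the list alone), with a median of -0.69 and a camera adjusted p of 1.17e-07 (adjusted p = 0.0445 with an estimated correlation). Errfi1, an inhibitor of the EGF receptor, was 9.84-fold lower, Junb 5.62-fold, the mRNA decay factor gene Zfp36 4.63-fold and Klf6 3.75-fold; the dimmest of the 3 target rows of Junb did not change (log2 0.028). Of 23 genes of the TLR4 receptor pathway, 8 fell and 0 rose (10 fell and 2 rose adjusted over the list alone), with a median of -0.40 and a camera adjusted p of 0.000119 (adjusted p = 0.0855 with an estimated correlation). The receptor genes Tlr2 and Tlr3 were 20.0-fold and 15.9-fold lower, and the adaptor genes Myd88 and Tirap were 5.45-fold and 3.99-fold lower.

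Genes of cell survival and of cell death were lower as groups. Of 21 cell survival genes, 6 fell and 1 rose (7 and 4 adjusted over the list alone), with a median of -0.45 and a camera adjusted p of 0.00025 (adjusted p = 0.0855 with an estimated correlation). The kinase gene Pim3 was 18.5-fold lower and Pim1 4.51-fold lower. Birc3 and Birc2, which encode inhibitors of death receptor signalling, were 7.11-fold and 6.14-fold lower. Cflar, which encodes the caspase-8 inhibitor c-FLIP, was 2.21-fold lower with an adjusted p of 0.0413, and passed with none of the 6 arrays left out (adjusted p between 0.0513 and 0.119). Bcl2, an anti-apoptotic gene, was 3.38-fold higher, and missed the threshold without LPS replicate 1 (adjusted p = 0.101) or 2 (0.0956) or LPS/GalN replicate 2 (0.088) or 3 (0.0575). It had 1 of 2 target rows past the threshold (log2 0.709 and 1.756). Of 30 death receptor and apoptosis genes, 7 fell and 1 rose (11 and 2 adjusted over the list alone), with a median of -0.45 and a camera adjusted p of 0.000138 (adjusted p = 0.0855 with an estimated correlation). The death receptor gene Fas was 4.11-fold lower, Ripk1 3.18-fold, Apaf1, the scaffold of the apoptosome, 4.24-fold (2 of 4 target rows past the threshold, log2 -2.083 to 0.001), and Casp2 7.90-fold. Fas had 1 of 2 target rows past the threshold (log2 -2.04 and -0.775), and Ripk1 had 1 of 3 (-1.668 to -0.773). Tnfrsf1b, the second TNF receptor gene, was 2.35-fold higher, and passed with none of the 6 arrays left out (adjusted p between 0.0539 and 0.141). Casp8, the initiator caspase gene, differed by -1.10 ± 0.31 (adjusted p = 0.114) and passed under 2 alternatives (lowest adjusted p = 0.011). The TNF receptor gene Tnfrsf1a differed by -1.01 ± 0.22 (adjusted p = 0.0508) and passed under 10 alternatives, all with the 6 arrays kept (lowest adjusted p = 0.000207, with trend and robust fitting).

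Of 22 coagulation regulators and endothelial activation genes, 6 fell and 0 rose (9 fell and 1 rose adjusted over the list alone), with a median of -0.42 and a camera adjusted p of 0.000589 (adjusted p = 0.0872 with an estimated correlation). Nos2, the inducible nitric oxide synthase gene, was 10.8-fold lower, the tissue factor gene F3 6.74-fold and the protease gene Adamts4 5.39-fold. Among 19 neutrophil markers, 3 fell and 0 rose (5 fell adjusted over the list alone), with a median of -0.44 and a camera adjusted p of 0.00111 (adjusted p = 0.453 with an estimated correlation). With 1 array left out this median lay between -0.975 and -0.211. The members that fell were S100a8 (3.15-fold), S100a9 (2.93-fold) and Lrg1 (2.65-fold), and hepatocytes also express Lrg1 as an acute phase gene. S100a8 missed the threshold without LPS replicate 2 or LPS/GalN replicate 2 (adjusted p up to 0.0657), S100a9 without these or LPS/GalN replicate 3 (up to 0.0681), and Lrg1 without any array but LPS/GalN replicate 3 (up to 0.11). The neutrophil call ended with LPS/GalN replicates 2 and 3 left out (median -0.017, adjusted p = 0.24).

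**Figure D3:**
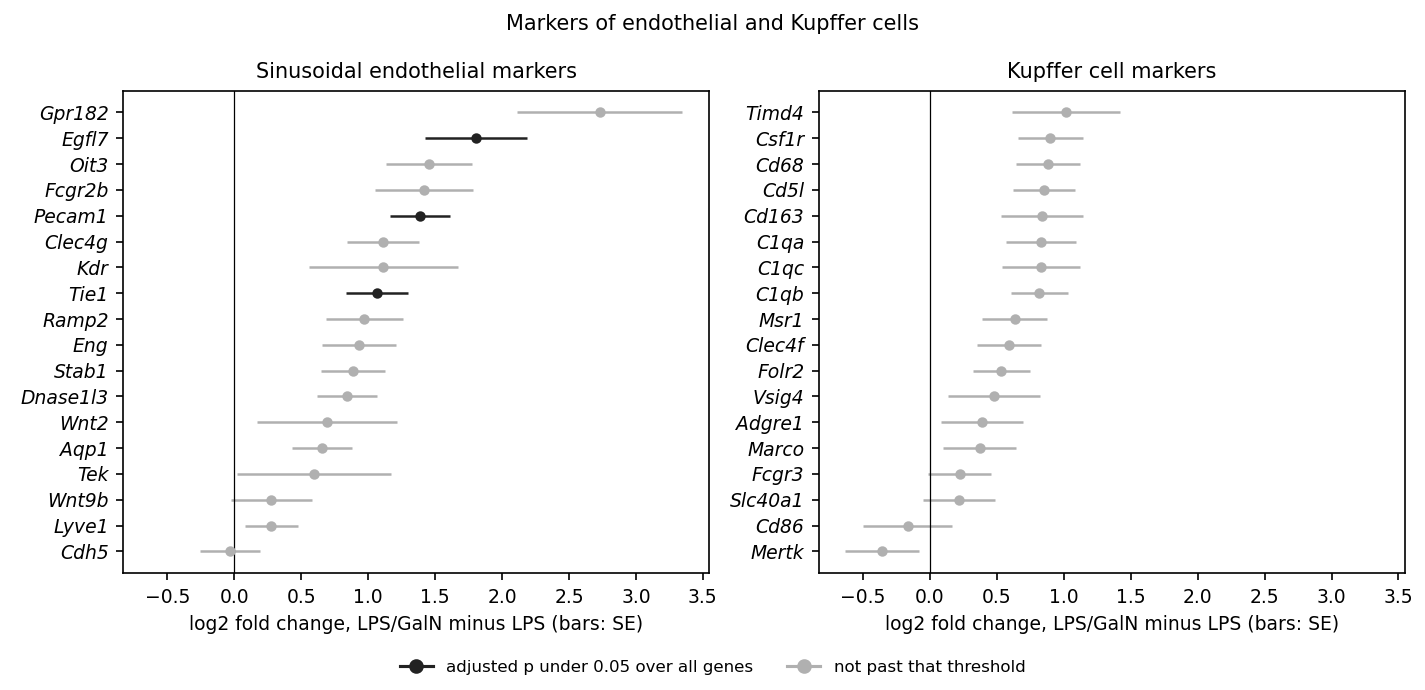
Log2 change of each measured marker of sinusoidal endothelial and Kupffer cells, LPS/GalN minus LPS (points) with its standard error (bars); black marks genes past the threshold over all genes. Pecam1, Egfl7 and Tie1 are the endothelial markers past it, and 0 of 18 Kupffer markers are.

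Markers of sinusoidal endothelial cells, which line the liver's capillaries, were higher. Of 18, 3 rose and 0 fell (12 rose adjusted over the list alone), with a median of 0.95 and a camera adjusted p of 1.74e-07 (adjusted p = 0.345 with an estimated correlation). Without LPS replicates 1 and 2, with the intestine markers high, the median was 0.664 (adjusted p = 0.00252), and without LPS/GalN replicates 2 and 3 it was 1.1 (adjusted p = 6.63e-07). Endothelial and Kupffer markers together were lower on LPS replicates 1 and 2 than on LPS replicate 3 by a median of -0.383, and in LPS/GalN replicate 1 against LPS replicate 3 their median was 0.51, against 0.829 over all arrays. The junction gene Pecam1 was 2.61-fold higher (9.58 ± 0.26 in LPS and 10.97 ± 0.016 in LPS/GalN), Egfl7, a secreted endothelial factor, 3.49-fold higher and the receptor gene Tie1 2.09-fold higher. These folds are of the brightest target row. Past the threshold were 2 of 3 rows of Pecam1 (log2 1.049 to 1.693), 1 of 2 of Egfl7 (1.167 and 1.805) and 1 of 2 of Tie1 (0.322 and 1.066). The call of Tie1 was lost with any of the 6 arrays left out (adjusted p between 0.0616 and 0.169), that of Egfl7 with any but LPS replicate 3 (between 0.0923 and 0.161), and that of Pecam1 without LPS replicate 1 (0.0712) or 2 (0.0685) or LPS/GalN replicate 2 (0.0531) or 3 (0.0502). Of 18 markers of Kupffer cells, the resident macrophages, 0 passed over all genes and 5 rose adjusted over the list alone, with a median of 0.61 and a camera adjusted p of 0.000138 (adjusted p = 0.217 with an estimated correlation). Of 13 monocyte markers, 0 passed over all genes or adjusted over the list alone (median 0.05, camera adjusted p = 0.637), and this median was -0.17 after centring on ribosomal protein genes. Of 17 markers of stellate cells and fibroblasts, 1 rose and 1 fell (1 and 1 adjusted over the list alone; median 0.21, adjusted p = 0.1); that list passed without LPS/GalN replicate 2 (median 0.40, adjusted p = 0.028) and with LPS/GalN replicates 2 and 3 left out (0.57, adjusted p = 0.0155).

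**Figure D4:**
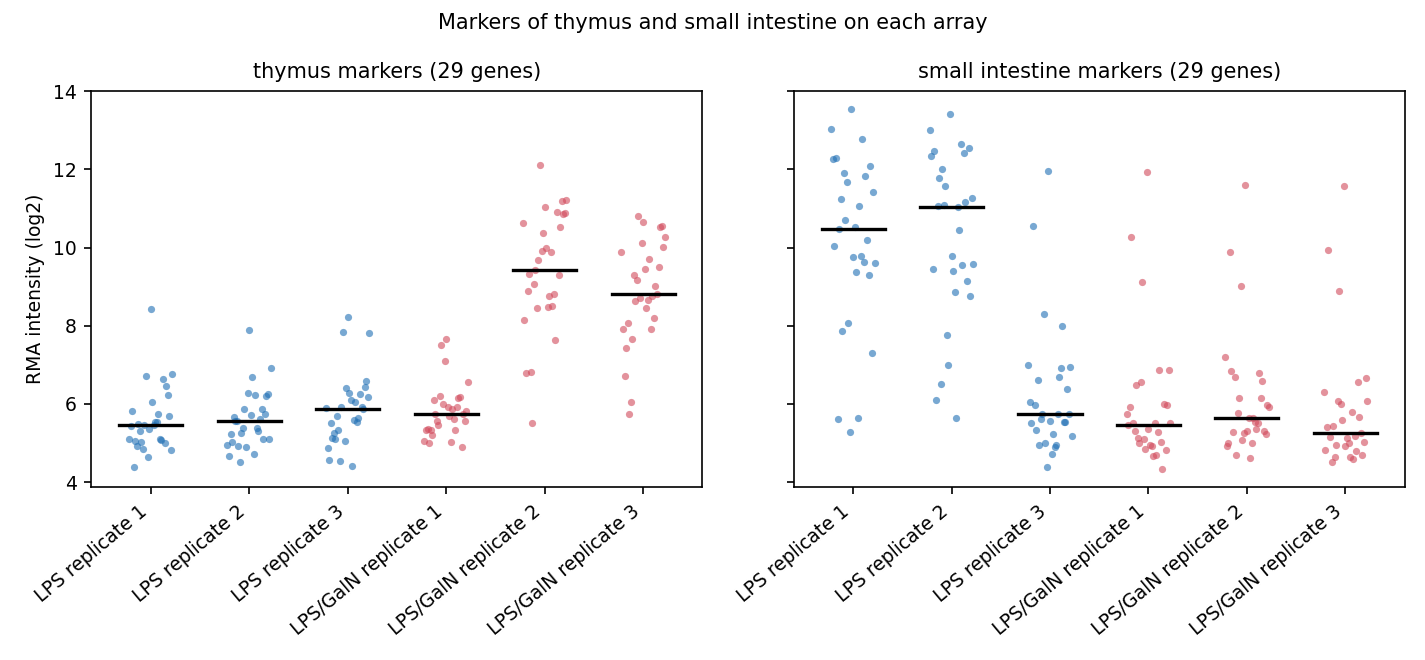
Log2 RMA intensity of 29 marker genes of thymus and 29 of small intestine on each array (points; blue, LPS; red, LPS/GalN) with their median (black line). Thymus markers have medians of 9.42 and 8.82 in LPS/GalN replicates 2 and 3, and intestine markers have medians of 10.48 and 11.03 in LPS replicates 1 and 2.

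Marker transcripts of other tissues were high on 4 arrays, in marker sets chosen after the values were seen. The median log2 intensity of 29 thymus markers was 9.42 in LPS/GalN replicate 2 and 8.82 in LPS/GalN replicate 3, and 5.46, 5.56, 5.87 and 5.75 on the other 4 arrays. The median of 29 small intestine markers was 10.48 in LPS replicate 1 and 11.03 in LPS replicate 2, and 5.73, 5.46, 5.64 and 5.25 elsewhere. Beside these values, 26 cell cycle genes had a median of 1.07, with 2 members that rose and 0 that fell over all genes and adjusted over the list alone, and a camera adjusted p of 2.18e-06 (adjusted p = 0.453 with an estimated correlation). Those members were Cdk2, a kinase of DNA replication onset, and Mcm5, a subunit of the replicative helicase. Cdk2 was 2.77-fold higher (adjusted p = 0.0338). Mcm5 was 4.14-fold higher (adjusted p = 0.0497), with 1 of 2 target rows past the threshold (log2 1.483 and 2.051). Both missed the threshold without LPS replicate 1 or 2 or LPS/GalN replicate 2 or 3 (adjusted p between 0.0966 and 0.161). Without LPS/GalN replicates 2 and 3 the median was 0.28, with an adjusted p of 0.161. Of 19 T, NK and B lymphocyte markers, 0 passed over all genes or adjusted over the list alone, with a median of 0.62 and a camera adjusted p of 0.00359 (adjusted p = 0.224 with an estimated correlation); without those arrays the median was 0.45, with an adjusted p of 0.519. Of 11 cholangiocyte markers (bile duct cells), 1 fell and 0 rose over all genes and adjusted over the list alone, with a median of -1.39 and a camera adjusted p of 0.0242 (adjusted p = 0.204 with an estimated correlation). The member that fell was Sox9, a transcription factor gene (7.53-fold). The cholangiocyte call ended without LPS replicate 1 (median -0.78, adjusted p = 0.0515) and without LPS replicates 1 and 2, with the intestine markers high (median -0.11, adjusted p = 0.306). It also ended without LPS/GalN replicates 2 and 3 (median -0.68, adjusted p = 0.0822), after centring on ribosomal protein genes (adjusted p = 0.0902), with features above the median only (adjusted p = 0.0594) and in the deposited value table (median 0.30, adjusted p = 0.441), where the lymphocyte call ended too (adjusted p = 0.675).

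Of the rises, 7 of targets with no gene name were larger than the smallest of the 10 genes given. The largest was that of a T cell receptor alpha chain transcript, singled out after its value was seen (16.3-fold, adjusted p = 0.0186). This transcript stood above all other arrays on LPS/GalN replicates 2 and 3, with the thymus markers high. Its call ended with any of 5 arrays left out (adjusted p up to 0.0839). Among named genes the largest rise was that of G6pc (chromosome 11, 101229043 to 101239217 on mm9), 15.6-fold, from 9.06 ± 1.91 in LPS to 13.02 ± 0.093 in LPS/GalN (adjusted p = 0.0375). Of the LPS arrays, replicates 1 and 2, with the intestine markers high, read 7.85 and 8.06, and replicate 3 read 11.26; without the first 2 the log2 change was 1.76 (adjusted p = 0.181). Slc25a30, a mitochondrial carrier gene (chromosome 14, 76168153 to 76186769), was 8.84-fold higher, from 6.89 ± 0.24 to 10.03 ± 0.25 (adjusted p = 0.000646). The transcription factor gene Mef2d was 6.25-fold higher (1 of 3 target rows past the threshold, log2 0.399 to 2.645), the beta-defensin gene Defb9 5.51-fold and Rpph1, the RNA of ribonuclease P, 4.96-fold. Genes of blood cells made up the other 5. Sla2, an adaptor that restrains T cell receptor signalling, was not above background on any LPS array and at least 8.60-fold higher in LPS/GalN (adjusted p = 0.0113). Parvg, an adhesion gene of blood cells, was 6.05-fold higher, the integrin activator gene Apbb1ip 5.63-fold (1 of 4 target rows past the threshold, log2 -0.38 to 2.492), Rcsd1 5.40-fold and the lymphocyte GTPase gene Gimap1 5.09-fold. On LPS/GalN replicates 2 and 3, with the thymus markers high, Sla2 read 9.31 and 8.35 against 6.85 on replicate 1, and Gimap1 read 8.21 and 8.05 against 6.72. With those arrays left out, the log2 change was 2.20 for Sla2, 1.27 for Parvg, 1.82 for Apbb1ip, 1.32 for Rcsd1 and 1.40 for Gimap1, and of the 10 rises Slc25a30 passed (adjusted p = 0.0262). With each array left out in turn, Slc25a30 passed each time, and each of the other 9 missed the threshold without at least 2 arrays, with adjusted p up to 0.153 (Parvg without LPS replicate 1).

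Regulators of hepatocyte identity went both ways. Of 26 hepatocyte transcription factors and nuclear receptors, 5 fell and 1 rose (10 and 4 adjusted over the list alone), with a median of -0.27 and a camera adjusted p of 0.0735. Nr5a2, a nuclear receptor gene of bile acid and cholesterol metabolism, was 4.78-fold lower, Foxa3 3.32-fold, Prox1 3.10-fold and Foxa1 3.93-fold, and Onecut1 was 4.79-fold higher. Foxa1 missed the threshold without any array but LPS/GalN replicate 1 (adjusted p between 0.0585 and 0.102), Prox1 without 4 arrays (up to 0.0853) and Onecut1 without 4 arrays (up to 0.119). The list itself passed without LPS/GalN replicate 1 (median -0.24, adjusted p = 0.025). Of 38 hepatocyte secreted proteins, 0 passed over all genes or adjusted over the list alone (median -0.01, adjusted p = 0.642). Of 31 cytochrome P450 and drug metabolism genes, 0 passed over all genes or adjusted over the list alone (median 0.27, adjusted p = 0.101); this list passed without LPS replicate 1 (adjusted p = 0.0299) and without LPS/GalN replicate 2 (adjusted p = 0.0383), and also with the mean of all target rows of a gene (0.0253), with trend and robust fitting (0.00379), with values floored at background (0.0436) and without LPS replicates 1 and 2 (0.029). Of 19 bile acid genes, 0 passed over all genes and 1 fell adjusted over the list alone (median -0.02, mean 0.05, adjusted p = 0.991, direction up). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 1.78 ± 0.53 (adjusted p = 0.133). It passed without LPS replicate 3 (2.44, adjusted p = 0.00921) and with trend and robust fitting (adjusted p = 0.0427). On LPS replicates 1 and 2, with the intestine markers high, Cyp7a1 read 5.79 and 6.38, against 8.05 on LPS replicate 3. Without LPS replicates 1 and 2 its log2 change was 0.47.

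Lists of energy metabolism did not pass the set test, except oxidative phosphorylation. Of 26 glycogen and glucose genes, 1 rose (G6pc) and 1 fell (1 and 3 adjusted over the list alone; median -0.17, adjusted p = 0.11). Of 22 fatty acid and triglyceride synthesis genes, 1 fell (1 rose and 1 fell adjusted over the list alone; median 0.27, adjusted p = 0.269), and of 27 fatty acid oxidation and ketogenesis genes, 1 fell, also adjusted over the list alone (median 0.12, adjusted p = 0.497). Of 26 cholesterol synthesis and uptake genes, 0 passed over all genes or adjusted over the list alone (median 0.18, adjusted p = 0.432); the list passed upward without LPS replicate 3 (0.32, adjusted p = 0.0103) and downward without LPS replicates 1 and 2 (-0.41, adjusted p = 0.0229). Of 30 pyrimidine and UDP-sugar genes, 1 fell, also adjusted over the list alone (median 0.02, mean -0.22, adjusted p = 0.578, direction down), and Ugp2, which makes UDP-glucose, differed by 0.40 ± 0.25 (adjusted p = 0.465). Oxidative phosphorylation genes (35, 0 past the threshold over all genes or adjusted over the list alone) had a median of 0.20 and a camera adjusted p of 0.0136, and ribosomal protein genes (49, 0 past it likewise) had a median of 0.22 and a camera adjusted p of 0.00315. With an estimated correlation the adjusted p was 0.595 for oxidative phosphorylation and 0.583 for ribosomal proteins. After centring on ribosomal protein genes, which moved the median change of all features from 0.05 to -0.17, the medians of these lists were -0.02 and -0.006, and both calls ended; cyclic loess also ended both (0.11 each, adjusted p = 0.142 and 0.0886). Without LPS replicate 3 the adjusted p was 0.129 for oxidative phosphorylation and 0.0517 for ribosomal proteins, and without LPS/GalN replicate 3 it was 0.0604 for oxidative phosphorylation. Without LPS/GalN replicates 2 and 3 it was 0.109 for oxidative phosphorylation and 0.307 for ribosomal proteins.

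Of 23 ribosome biogenesis genes, 3 fell and 0 rose (5 fell adjusted over the list alone), with a median of -0.17 and a camera adjusted p of 0.0257 (adjusted p = 0.505 with an estimated correlation). The nucleolar genes Nop58, Rrs1 and Wdr43 were 4.09-fold, 4.45-fold and 3.79-fold lower, and Wdr43 missed the threshold without any LPS array or without LPS/GalN replicate 2 (adjusted p between 0.0635 and 0.0994). The call of this list ended without LPS replicate 2 (adjusted p = 0.0796), LPS replicate 3 (0.0955) or LPS/GalN replicate 1 (0.0844), after further quantile normalization (0.0658) and with features above the median only (0.0628). Of 32 genes of transcription and RNA processing machinery, 1 fell, also adjusted over the list alone (median -0.06, adjusted p = 0.498); this list passed without LPS/GalN replicates 2 and 3 (median -0.19, adjusted p = 0.0304).

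Stress-response lists held few changed members. Of 21 integrated stress response genes, 2 fell (1 rose and 5 fell adjusted over the list alone; median -0.12, adjusted p = 0.111), among them Atf3, a stress-induced transcription factor gene, which was 15.2-fold lower (adjusted p = 0.00059). Of 19 p53 target genes, 2 fell (7 adjusted over the list alone), with a median of -0.06 and an adjusted p of 0.11. The cell cycle inhibitor gene Cdkn1a differed by -1.34 ± 0.45 (adjusted p = 0.174) and passed without LPS/GalN replicate 1 (adjusted p = 0.0172). That array read 11.255, within the LPS values of 11.17 to 11.98, and LPS/GalN replicates 2 and 3, with the thymus markers high, read 9.74 and 9.64. Without LPS/GalN replicates 2 and 3 the log2 change of Cdkn1a was -0.30. The integrated stress response list passed without LPS replicate 1 (adjusted p = 0.0359) and the p53 list without LPS/GalN replicate 1 (adjusted p = 0.031). Without LPS/GalN replicates 2 and 3 the median of the p53 list was -0.001. Of 19 ER chaperone and unfolded protein response genes, 1 fell (2 rose and 1 fell adjusted over the list alone; median 0.15, adjusted p = 0.203), and of 18 heat shock genes, 2 fell, also adjusted over the list alone (median -0.15, adjusted p = 0.247). Of 24 NRF2 and antioxidant genes, 1 fell, also adjusted over the list alone (median 0.14, adjusted p = 0.653). The medians of the ER chaperone and NRF2 lists were below 0 after centring on ribosomal protein genes (-0.07 and -0.08).

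Of 18 circadian clock genes, 2 rose and 1 fell (3 and 2 adjusted over the list alone; median -0.11, adjusted p = 0.678). Cry1 was 2.31-fold higher and Bhlhe40 was 5.28-fold lower, and the call of Cry1 ended with any of the 6 arrays left out (adjusted p between 0.0747 and 0.0974). Of 21 BMP and TGF-beta target genes, 2 fell (1 rose and 3 fell adjusted over the list alone; median -0.37, adjusted p = 0.452). Of 11 red blood cell markers, 0 passed over all genes and 1 fell adjusted over the list alone (median 0.35, mean 0.06, adjusted p = 0.692), and of 16 adipose and pancreatic markers, 0 passed over all genes or adjusted over the list alone (median -0.28, adjusted p = 0.435). Of the 20 lists past the set test, 14 fell and 6 rose; NF-kB, immediate early and signal inhibitor genes were the 3 that passed with an estimated correlation, and fry passed 16 lists, with the integrated stress response and hepatocyte transcription factor lists added and the ribosome biogenesis, ribosomal protein, oxidative phosphorylation, cell cycle, neutrophil and lymphocyte lists lost.

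Members behind counts of 5 or fewer that the naming rule left out are given here, chosen after their values were seen. Lower past the threshold over all genes were Pfkfb3, a glycolysis regulator (19.4-fold, adjusted p = 0.00027), the heat shock genes Bag3 (8.28-fold, 0.000671) and Hspa1b (4.48-fold, 0.00664), Xbp1 of the unfolded protein response (5.64-fold, 0.00372), Ppp1r15a of the integrated stress response (4.58-fold, 0.00175), the BMP and TGF-beta targets Id3 (4.21-fold, 0.0025) and Skil (2.65-fold, 0.0353), Angptl4 of the fatty acid oxidation list (4.14-fold, 0.00884), Elovl6 of fatty acid synthesis (2.51-fold, 0.0272), Hmox1 of the NRF2 list (4.03-fold, 0.00944), the p53 targets Gadd45a (3.97-fold, 0.00332) and Plk3 (2.17-fold, 0.0255), Taf7 of transcription (3.16-fold, 0.0141), Upp2 of pyrimidine metabolism (3.11-fold, 0.0374), the hepatocyte factor gene Foxa2 (6.85-fold, 0.026) and Timp1 of the stellate cell list (3.23-fold, 0.00883). Ngfr of the stellate cell list was 2.75-fold higher (0.0143). With each array left out in turn, Skil, Foxa2, Plk3 and Upp2 missed the threshold without 5 arrays, Elovl6 without 4, Ngfr and Taf7 without 2 and Hmox1 without 1 (adjusted p up to 0.0511), and the others passed each time. Members that passed only adjusted over the list alone were, upward, Cd68, C1qa, Cd5l, Csf1r and C1qb (Kupffer cells), Akt1, Birc5 and Bcl2l2 (survival), Bik (death), Tlr1 and Tab2 (TLR4), Nr1h3, Nr2f2 and Nr2f1 (hepatocyte factors), Herpud1 and Ern1 (unfolded protein response), Phgdh (integrated stress response), Clock (clock), Lpin2 (fatty acid synthesis), Esm1 (endothelial activation) and Tgfb1 (BMP and TGF-beta). Downward they were Mthfd2, Chac1 and Atf4 (integrated stress response), Hk2 and Ppp1r3b (glucose), Clec4e and Mmp8 (neutrophils), Rrp9 and Rrp1b (ribosome biogenesis), Nfil3 (clock), Baat (bile acids), Fst (BMP and TGF-beta) and Epb42 (red blood cells).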

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

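Alternatives added only after seeing the data were symbol-only joining, the background floor and leaving out the arrays with transcripts of other tissues; the others were planned. The 1073 falls stayed within 1.5 times under every scaling, filter, joining, weighting and fitting alternative run. Rises (at least 2-fold rises in brackets) moved further: 124 (123) after centring on ribosomal protein genes, 495 (331) with features above the median, 891 (454) with trend and robust fitting, and 630 in the deposited value table, against 218 (214). Fewer features were tested in the filtered set and in the table; the other causes were not tested. At an adjusted p under 0.01 there were 21 rises and 587 falls. With each array left out in turn, rises ranged from 35 to 616, falls from 620 to 1084, at least 2-fold rises from 35 to 616, at least 2-fold falls from 620 to 1084, and lists past the set test from 18 to 22. The extreme values came without LPS replicate 1 (35 and 620), LPS/GalN replicate 1 (616) and LPS replicate 3 (1084). Leaving out the arrays with thymus transcripts gave 21 rises and 238 falls, all at least 2-fold, of which 3 (Slc25a30, Onecut1 and a hypothetical gene) and 229 were among the genes called with all arrays. Leaving out those with intestine transcripts gave 0 in each direction by limma at either size, with 3265 features at an unadjusted p under 0.05. Both leave 1 array in a group, which is assumed to vary like the others, and fewer samples lower the power. With an estimated correlation 3 of 20 lists passed.

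The replicate block gave 112 rises (112 at least 2-fold) and 805 falls, 78 and 780 of them shared with the unblocked calls, and all 20 lists kept their side. Deviations of same-numbered arrays correlated at 0.003, -0.002 and 0.026, so the numbers were not taken to pair the mice.

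By the direction of the test, 3 values past the threshold with or without the change reversed: Saa3 (0.007) and Junb (0.028) by their dimmest target, when targets were tested separately, and the cholesterol synthesis list (-0.41) without the intestine arrays; the cause was not tested. Of 39 called named genes with several targets, 23 had each target past the threshold, and 4 had one of the opposite sign (Apbb1ip at -0.38 and Apaf1 at 0.001 besides those above). Where neither value passed, 12 gene and 26 list values changed direction. Medians of called lists changed sign in 4 further cases, with the call lost: cholangiocytes (0.30) in the deposited table, ribosomal proteins (-0.006) and oxidative phosphorylation (-0.02) after centring on ribosomal protein genes, and ribosome biogenesis (0.01) without LPS/GalN replicate 1. Named genes missed the threshold in 192 of 1452 comparisons with other alternatives (89 of them without the intestine arrays, 48 without the thymus arrays) and passed it anew in 13. With single arrays left out they missed it in 120 of 588; 58 of 68 falls and 2 of 21 rises (Slc25a30 and Spry1) passed each time. Signal over background limits dim genes: 31 called features were not above background in 1 group.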

Other observations

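Further genes that belong to the described responses lay outside the fixed lists, and were chosen after their values were seen. Ripk2, a kinase of bacterial peptide sensing, was 21.8-fold lower in LPS/GalN (12.37 ± 0.18 in LPS and 7.93 ± 0.33 in LPS/GalN, log2, SD, n = 3 each; adjusted p = 0.000259 by limma), and Ikbke, a kinase of interferon induction, was 6.40-fold lower (adjusted p = 0.00198). Tiparp, a target of the aryl hydrocarbon receptor, was 19.8-fold lower, the cyclic AMP phosphodiesterase gene Pde4b 17.8-fold and Adm, which encodes the vasodilator adrenomedullin, 17.2-fold. The receptor gene Acvrl1 (4.57-fold, adjusted p = 0.0158), Cd300lg (2.97-fold, adjusted p = 0.0241) and Pde2a (2.43-fold, adjusted p = 0.0278), known from endothelial cells, were higher; endothelial genes outside the list were not tested as a group. The noncoding RNA genes Snora15 (4.87-fold, adjusted p = 0.00956) and Snhg20 (3.32-fold, adjusted p = 0.00449) were higher as well.

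On LPS/GalN replicate 1 alone, several liver genes that were also chosen after their values were seen had high values. A1bg read 10.14 on that array against 5.25 to 6.77 on the other 5. Gpc3 read 9.51 against 5.82 to 7.12, Hsd17b13 read 8.92 against 5.32 to 6.14, and Sult2a1 read 7.05 against 4.94 to 5.76. A1bg and Sult2a1 are known from female mouse liver, and Xist, the transcript of the inactive X chromosome, read between 5.26 and 6.42 on the 6 arrays. The labels of that sample do not differ from those of its group.

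The 6 arrays split into groups of 3 in 10 ways, too few for chance to be judged at the 0.05 level. The labelled split was the 1 of 10 splits with the largest value for each count. It gave 218 rises and 1073 falls, with 214 and 1068 of at least 2-fold, and the highest other split gave 0 for each of the 4 counts. It gave 20 lists past the set test, and the highest other split gave 12.

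Of the tests in the next 3 paragraphs, those of scaling were fixed before their results were seen; the others were chosen only afterwards.

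Transcripts that LPS is known to raise (acute phase, cytokine, chemokine, NF-kB and interferon-stimulated lists, 143 genes) were lower in LPS/GalN. Each list passed camera with the preset correlation. With an estimated correlation the NF-kB list passed (adjusted p = 0.0445) and the others did not (adjusted p between 0.0872 and 0.108). The median log2 change was still -1.63 under the scaling that brought it nearest to 0. The deposited values were already normalized, and the scalings moved the median change of all features from 0.053 to -0.169 at most. The values therefore argue only against a remaining shift between arrays of the size these scalings correct. They cannot test the normalization already applied. Markers of macrophages and monocytes gave no sign of a loss of these cells, with a median change of 0.386 and 25 of 31 higher. After centring on ribosomal protein genes that median was 0.163 (quartiles -0.188 and 0.606). Monocyte markers alone had a median of 0.048. Marker levels are not cell counts, so a loss cannot be excluded. RNA of small intestine in LPS replicates 1 and 2 would have put these genes higher there than in LPS replicate 3, and the median difference was 0.006 (quartiles -0.203 and 0.173). A candidate explanation that stays open, as a hypothesis, is that GalN, by lowering uridine nucleotides, may keep hepatocytes from making newly induced transcripts while long-lived ones persist; it was not tested, since no untreated mice and no mice given GalN alone were analysed here.

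Markers of endothelial and Kupffer cells were higher in LPS/GalN (36 genes, median 0.829), with 3 of 18 endothelial and 0 of 18 Kupffer markers past the threshold over all genes and neither list past the set test with an estimated correlation (adjusted p = 0.345 and 0.217). The lowest median over the scalings was 0.606, which again argues only against a remaining shift of the size these scalings correct. The values argue against RNA of thymus, since the markers were not higher on the arrays with thymus transcripts. Their median difference from LPS/GalN replicate 1 was -0.142 (quartiles -0.263 and 0.055). A lower share of hepatocyte RNA would raise the markers of other non-hepatocyte types alike and stays open: 49 markers of monocytes, neutrophils and stellate cells had a median of -0.006, a difference of 0.834 (two-sided permutation p = 1e-04 over genes, the smallest that 10000 shuffles can give; genes are not independent replicates), but neutrophil markers respond to LPS themselves, and the quartiles of monocyte and stellate markers (-0.038 and 0.605) overlapped those of the endothelial and Kupffer markers (0.454 and 0.984). RNA of small intestine in LPS replicates 1 and 2 stays open as part of the cause, since the markers were lower there than in LPS replicate 3 by a median of -0.383 (quartiles -0.667 and -0.149); in LPS/GalN replicate 1 against LPS replicate 3, arrays with neither tissue, their median was 0.51, that of monocyte and stellate markers 0.222. A change in these cells themselves, in number or in transcription, remains a hypothesis that may be followed up by cell counts.

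Transcripts of thymus on LPS/GalN replicates 2 and 3 and of small intestine on LPS replicates 1 and 2 may come from other tissue taken along with the liver. Among 7 genes restricted to thymocytes and thymic epithelium, 6 lay above all other arrays (median difference 2.96; Aire did not), and among 19 restricted to the intestine 17 did (4.28; Fabp6 and Cdx2 did not). Of the thymus genes, Tcf7 read 12.11 and 10.82 and Lck 11.21 and 10.27, and of the intestine genes Vil1 read 13.04 and 13.02 and Guca2b 12.79 and 12.65; 9 of 29 genes in each full set lay above the median of all features on the other 4 arrays, and 6 thymus genes are also in a fixed lymphocyte list. On the arrays with thymus transcripts, 7 B and NK cell markers differed by a median of 0.27, which gives no sign of more B or NK cells. These markers read low, with medians of 5.22 to 6.34 per array, and do not cover T cells. Mature T cells in the liver would not bring the 7 genes restricted to thymocytes and thymic epithelium. The median difference of these genes, 2.96 (quartiles 1.28 and 3.3), argues against mature T cells as the only source. Whether mature T cells add to the other thymus markers stays open, and so does more bile duct tissue. The 5 bile duct markers not known from intestinal epithelium differed by -0.45, but all 11 cholangiocyte markers differed by 1.90. Among the latter, Krt19, Epcam, Cldn4 and Cldn7, which intestine also expresses, were high on LPS replicates 1 and 2. In the 2 arrays with neither set, LPS/GalN replicate 1 and LPS replicate 3, all 218 called rises and 1073 called falls had the same direction, which is not independent of the calls, and 151 of the rises and 1018 of the falls were at least 2-fold; the interferon-stimulated list differed by -2.49, and cell cycle genes by 0.12 against 1.07 over all arrays.

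Pairs of arrays also differed in how many features stood more than 1.5 (log2) above all other arrays: 210 for LPS replicates 1 and 2, 205 for LPS/GalN replicates 2 and 3, and 0 to 15 for the other 13 pairs. Of the 205, 3 were among the called rises: Parvg, a T cell receptor alpha chain transcript and a transcript similar to the chemokine TCA4. Of the 210, 1 was among the called falls, Fbp2, a fructose bisphosphatase gene. Except for Parvg, these were named after their values were seen.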
